A study of Geobacter sulfurreducens PCA with 3 samples.

How the data were processed

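The 3 libraries captured the 5′ ends of primary transcripts, per the labels' protocols. Total RNA was treated with an exonuclease that removes RNA with a 5′ monophosphate, which processed and degraded RNA carries. The remaining 5′ triphosphate ends, which mark newly started transcripts, were converted to monophosphate ends and ligated to an adapter. cDNA of 100 to 300 bp was purified, amplified by PCR and sequenced on an Illumina Genome Analyzer II, per the series' design text and the labels. The protocols name no molecular identifier, so reads from 1 amplified molecule cannot be separated from reads of several molecules.

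The authors deposited 1 alignment file per library, with 1 line per read and a count of 1 on every line, described in the deposited readme as the unedited output of the Mosaik aligner. The aligner's version and settings are not given in the sources used here. Files are named as holding unique alignments. The files name the chromosome NC_002939 without a version, and the readme names version NC_002939.4 for the position tracks of the series, which were not used here. Positions are given as in the files, 1-based. The 5′ end was the left end of plus-strand reads and the right end of minus-strand reads. The recorded right end could be off by 1 nt for minus-strand reads, which was not settled without the genome sequence. Read names put the electrode and fumarate libraries on 1 instrument (lanes 6 and 7) and the N2 library on another (lane 7), with reads from 70, 22 and 100 tiles. Within a library, odd and even tiles differed by close to counting error, with a mean chi-square per position of 1.05, 1.01 and 0.98 where counting error alone gives 1. Both sets of tiles hold reads of the same amplified library, so PCR copies would not show here.

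The planned analysis was by gene: reads up to 300 nt upstream of each start codon, classes of start sites, leader lengths, start base composition and medians of fixed gene lists. None of this was run. The reference table at hand describes another assembly (ASM798v2), without strand, and coordinates were not carried between assemblies, so no site was assigned to a gene and the gene-based parts of the rule for named genes were not applied. The start site took the place of the gene, and scaling by reads outside ribosomal and transfer RNA genes was replaced by scaling to all aligned reads (reads scaled to library size, RPM), which had been listed beforehand as another setting.

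A start site was a run of positions with at least 10 reads, joined on 1 strand when at most 5 nt apart, and named by its position with most reads. The term rests on read counts alone, and whether a site was a primary start or a processed end was not tested. For comparisons, positions with 10 reads in any library were joined into 2129 sites, and every library's reads were summed over them. Sharing was counted within 5 nt after thinning each library to 123905 reads, as the mean of 20 draws with the exact interval of the first draw, and set beside 100 shifts of 1 library's sites along the genome. Ratios of RPM have exact conditional Clopper-Pearson 95% intervals. A site was called higher or lower with at least 20 reads in the pair and the interval bound nearest to 1 at 4-fold or beyond. This is a size rule, not a test. For the comparisons with fumarate, the text names sites from the 12 highest and 12 lowest by that bound and draws on the 10 leading sites per library. The 10 leading sites were planned before the data were examined. The 12 highest and 12 lowest were planned for genes, and were carried over to sites because the gene analysis could not be run. Minus 3587365, plus 1507900 and minus 3101590 fall outside these lists and were chosen after their values were seen. A ratio against 0 reads was computed against a floor of 3 reads in that library and is given as at least that fold. This floor is 3.94 RPM in the electrode, 24.2 in the fumarate and 22.4 in the N2 library. The lower end of the exact interval, used for calls and ranks, is smaller: at minus 2031398 it was 210.6 against 259.1 for electrode over fumarate.

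The measure for regions was chosen after the data were seen: the number of distinct 5′ positions per 1000 nt and strand, scaled by each library's distinct positions, with the same size rule. It counts each position once, so a heavily amplified molecule adds 1. Called bins with at most 1 uncalled bin between them were joined. Bins of 200 and 5000 nt and a 2-fold bound were also looked at.

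On simulated counts for the 2129 sites with 200 changed, the size rule recovered 81% of 8-fold and 94% of 20-fold changes for the electrode comparison, and 73% and 91.5% for the N2 comparison, with 0 calls among unchanged sites. The changed sites were drawn in proportion to their share of reads, so recovery was measured mostly at sites with many reads. The simulated counts held counting error only, with no PCR copies, so the 0 calls do not measure errors from amplification. The site finder recovered 300 of 300 planted sites, all planted above its read minimum. Other settings covered the read minimum (5 and 50), joining (20 nt), sharing distance, depth, scaling, the minimum of the pair and the fold bound. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.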

Results

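Transcript starts were mapped in Geobacter sulfurreducens PCA, an anaerobic soil and sediment bacterium that can pass electrons from acetate to solid acceptors such as an electrode. The series holds 3 libraries, 1 for each growth condition, all from wild-type cells grown without oxygen at 30 °C. The electrode library came from cells grown on an electrode and harvested after 1 week. The fumarate library came from mid-exponential cells in acetate-fumarate medium, in which dissolved fumarate accepts the electrons. The N2 library came from mid-exponential cells in the same medium with nitrogen gas as nitrogen source, which this organism can use through nitrogenase. The electrode library held 761274 aligned reads, the fumarate library 123905 and the N2 library 133646. These reads began at 48132, 28839 and 27513 distinct positions respectively. With 1 library per condition there is no replicate spread, so no difference between conditions was tested. Intervals of ratios and shares are exact 95% intervals that cover counting error only, since PCR copies of a molecule are counted as separate reads.

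A few start sites took a large part of every library. The site on the minus strand at 1874451 led the electrode library with 10.8% of reads and the N2 library with 10.4%, and held 2.50% of the fumarate library. On the opposite strand, a plus-strand site peaking at 1874402 (1874338 to 1874446) held 0.726%, 1.73% and 3.005% of the electrode, fumarate and N2 libraries. The plus-strand site at 528503 also stood high in the electrode library (4.70%) and the N2 library (5.33%), against 0.546% in the fumarate library. The plus-strand site at 1603527 was mainly an electrode site, with 6.36% of that library, 1.12% of the fumarate library and 0.828% of the N2 library. The minus-strand site at 3147456 was also highest in the electrode library, with 3.31% in the electrode library, 0.220% in the fumarate library and 0.705% in the N2 library. The fumarate library was led by the plus-strand site at 3555956, with 9.30% of its reads, against 0.300% of the electrode library and 0.0284% of the N2 library. It was followed by plus 648060 with 3.83% (0.310% in the electrode and 1.02% in the N2 library) and plus 1195869 with 3.05% (0.774% and 2.21%). Plus 2083319 was among the 10 leading sites of all 3 libraries, at 1.38%, 1.98% and 2.91%. Among the 10 leading N2 sites, minus 337299 held 1.53% of that library and minus 3388234 held 1.18%, while both stayed under 0.2% of the other libraries.

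**Figure D1:**
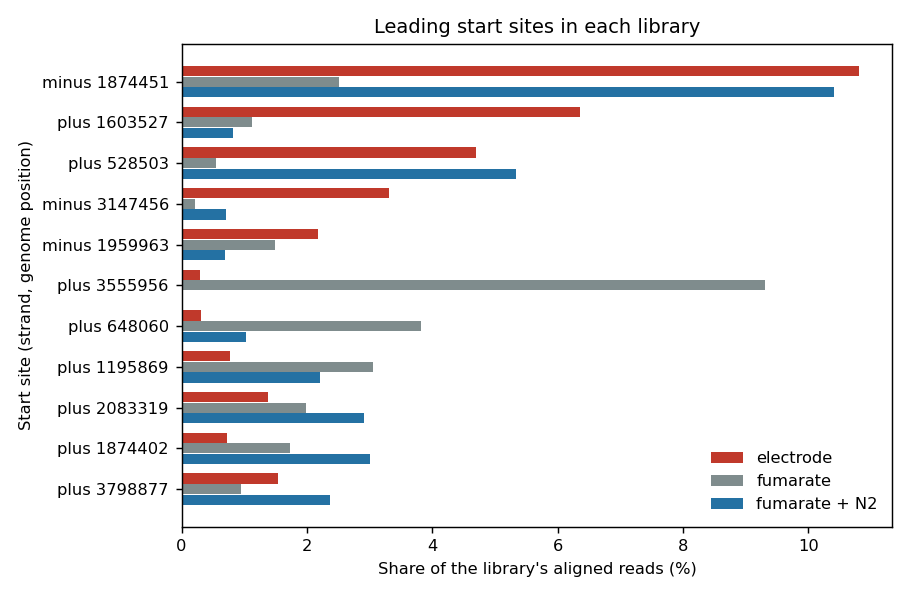
Bars give the share of each library's aligned reads, in percent, at the 5 leading start sites of the electrode, fumarate and N2 libraries, named by strand and position. Minus 1874451 leads the electrode and N2 libraries at 10.8% and 10.4%, while plus 3555956 leads the fumarate library at 9.30%.

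The number of start sites and their overlap were compared to ask how far the conditions used the same transcript starts. As deposited, 1552 start sites were found in the electrode library, 782 in the fumarate library and 778 in the N2 library. With every library thinned to 123905 reads, the electrode library gave 702.5 sites on average over 20 draws and the N2 library 747. At that number of reads 57.2% of electrode sites (54.1 to 61.5) had an N2 site within 5 nt, and 38.4% (34.8 to 42.2) had a fumarate site. Of the fumarate sites, 34.8% (31.2 to 38.0) were found in the electrode library and 32.8% (29.2 to 35.9) in the N2 library. Under every other setting tried, more electrode sites were found in the N2 than in the fumarate library. Sites shifted along the genome matched about 0.1% of the time. On average 227.6 sites were shared by all 3 libraries. Where regions of joined starts held at least 20 reads in both thinned libraries, the electrode and N2 libraries had the same leading position in 265 of 294 (90.1%, 86.1 to 93.3). The electrode and fumarate libraries did so in 175 of 231 regions (75.8%, 69.7 to 81.1), and the N2 and fumarate libraries in 153 of 220 (69.5%, 63.0 to 75.6). Equal reads need not be equal molecules: the thinned electrode reads fell on 11446 positions against 28839 in the fumarate and 25901 in the N2 library, with 87.9%, 67.7% and 72.8% of reads in start sites. The fumarate library was the most uneven by strand, with 61.2% of reads on the plus strand against 50.2% in the electrode and 51.4% in the N2 library.

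Growth on the electrode was set against growth with fumarate, to ask which starts go with the solid electron acceptor. The cells also differed in surface growth and in harvest, at 1 week against mid-exponential phase, so the acceptor cannot be told apart from these. The clearest electrode region was a stretch of 7000 nt on the minus strand, 3584001 to 3591000. Reads there began at 965 distinct positions in the electrode library (3668 reads), at 1 in the fumarate library and at 7 in the N2 library, a share of positions 578-fold (104 to 22861) above fumarate. Whether positions in this and the other stretches, inside or outside start sites, are transcript starts or leftover fragments was not tested. Its leading minus-strand site, 3587365, had 830 electrode reads and 0 in both other libraries. On the plus strand, 1508001 to 1512000 held 351 electrode positions against 13 in fumarate and 12 in N2, 16.2-fold above fumarate (9.34 to 30.7), with site 1507900 just upstream at 925 electrode reads against 1 fumarate read and 21 N2 reads. In the other direction, 12 bins were called over 14000 nt of the plus strand, 368001 to 382000. That whole stretch, uncalled bins included, held 1086 fumarate positions against 217 in the electrode library, 8.35-fold (7.21 to 9.71) by share of positions. The N2 library held 323 positions there, and only the bin from 377001 to 378000 was called between fumarate and N2. The minus-strand stretch 2757001 to 2761000 held 234 fumarate positions against 14 electrode and 5 N2 positions, 27.9-fold (16.3 to 51.8) above the electrode library. The plus-strand stretch 1880001 to 1882000 held 84 fumarate positions against 4 in the electrode and 1 in the N2 library, 35.05-fold (13.2 to 131.6) above the electrode library.

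At single start sites, of 1449 with at least 20 reads in the pair, 229 were higher in the electrode library and 284 were lower, by a size rule that asks for the interval bound nearest to 1 at 4-fold or beyond. Among the 229 higher sites, 112 had no fumarate read, and 114 of the 284 lower sites had no electrode read. Folds at sites, here and in the other comparisons, are ratios of reads. PCR copies count as reads, so these folds are not bounds on a difference in transcript starts. Many of the sites named cover a single position, where copies of 1 molecule would also fall. The site ranked first among the higher ones, minus 2031398, had 4776 electrode reads and none in the other libraries, at least 259-fold higher than fumarate. Minus 30395 followed with 3645 electrode reads, at least 198-fold, and plus 3589450 with 1904 reads, at least 103-fold, inside the electrode stretch of the minus strand but on the opposite strand. Minus 909782, plus 1712504, minus 104330, plus 1666852, minus 1913708 and minus 138439 had between 1007 and 1831 electrode reads and none in fumarate. Minus 1555426 had 2473 electrode reads against 2 fumarate reads, 201-fold (55.7 to 1663), plus 1669589 had 1553 against 1, 252.8-fold (45.3 to 9990), and minus 1537988 had 2735 against 4, 111-fold (43.4 to 408.7). Among the lower sites, plus 2268271 had 855 fumarate reads and 0 in both other libraries, at least 1751-fold lower in the electrode library. Minus 808609 had 817 fumarate reads and again none elsewhere, at least 1673-fold lower. Plus 225181, minus 3302309, plus 2290406, plus 1824566 and minus 2193622 had 183 to 352 fumarate reads and no electrode read. Minus 2249749 (586 fumarate reads), minus 2079142 (433) and plus 1611392 (259) had 1 electrode read each, and plus 1610115 (625) and minus 751 (544) had 3 each. Beside some sites the other library was not silent. Within 100 nt of minus 1555426 there were 470 further fumarate reads (3793 RPM) against 560 electrode reads (735.6 RPM), so its ratio is that of 1 position and not of its surroundings. In RPM the surroundings ran the other way at 6 of the 12 higher sites named, the others being minus 2031398 (217.9 RPM fumarate against 27.6 electrode), minus 104330 (371.3 against 28.9), plus 1669589 (64.6 against 18.4), minus 909782 (64.6 against 39.4) and minus 138439 (1 fumarate read against 0). Among the lower sites, plus 1611392 had 101 electrode reads and 222 fumarate reads within 100 nt, and the others had at most 14 electrode reads; at 2 of the 12, minus 751 and minus 2193622, the surroundings held 1 electrode read against 0.

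The 229 sites with at least 20 reads in both libraries had a median ratio 1.49-fold above 1, a shift of 0.58 on the log2 scale, and 73 of them lay within 2-fold. Scaling to that median left 155 sites higher and 300 lower, so the higher share of called sites went from 44.6% to 34.1%. A minimum of 100 reads left 220 higher and 67 lower sites, which turns the balance round. That minimum counts raw reads, so it removes more of the sites high in the smaller fumarate library. With libraries thinned to the same number of reads, 208 sites were higher and 256 lower. After thinning to the same number of reads, 9 of the 14 electrode-higher bins and 7 of the 23 electrode-lower bins were kept.

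**Figure D2:**
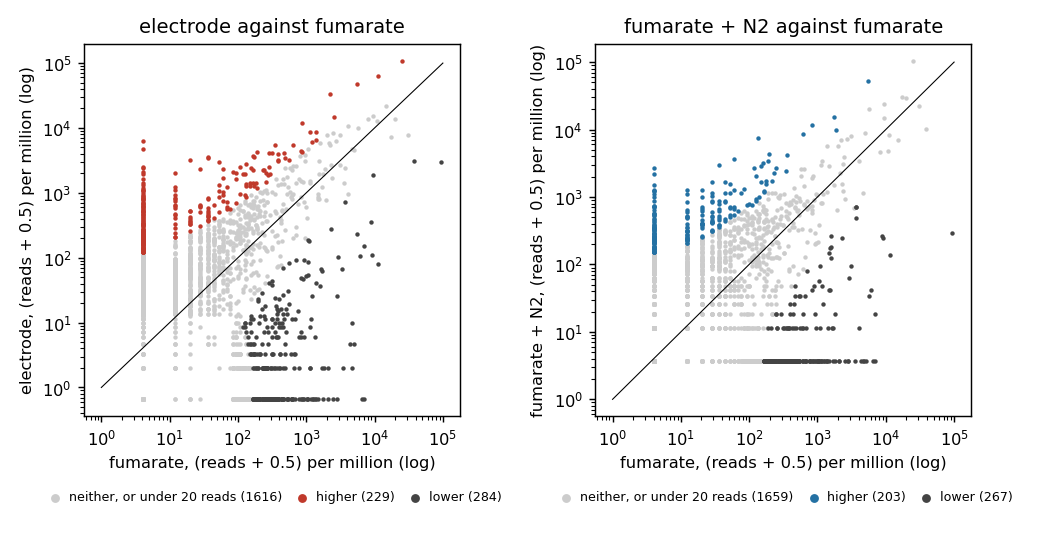
Each point is 1 of 2129 start sites, placed by reads plus 0.5, as RPM, in the fumarate library (horizontal, log scale) and in the electrode or N2 library (vertical, log scale), with a line at equal values. Coloured points are the 229 electrode-higher and 203 N2-higher sites, dark points the 284 and 267 lower sites, and columns or rows of points at the low edge are sites with 0 reads in that library.

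Growth with nitrogen gas as nitrogen source was set against the fumarate library of the same medium, to ask which starts go with the use of N2. The N2 and fumarate libraries were read on different instruments, so the nitrogen source cannot be told apart from instrument or preparation. Several stretches were read mostly or almost only in the N2 library. On the plus strand, 842001 to 848000 held 496 N2 positions against 25 in fumarate and 46 in the electrode library, 20.8-fold (13.9 to 32.45) above fumarate. On the minus strand, 3100001 to 3105000 held 212 N2 positions against 1 in fumarate and 2 in the electrode library, 222-fold (39.5 to 8818), and site 3105876 upstream of it had 296 N2 reads, 0 fumarate reads and 1 electrode read. Within that stretch, however, minus 3101590 had 607 electrode reads at a single site and 0 in both other libraries. The nearby minus-strand stretch 3083001 to 3087000 held 114 N2 positions, 1 fumarate and 0 electrode positions, and 3078001 to 3079000 held 34 N2 positions and none in the other libraries. On the plus strand, 1008001 to 1012000 held 180 N2 positions against 2 in fumarate and 8 in the electrode library, 94.3-fold (25.7 to 784.9). The minus-strand stretch 2757001 to 2761000, higher in fumarate than in the electrode library, was also higher than in the N2 library, 44.6-fold (18.9 to 138.8), as was plus 1880001 to 1882000, 80.1-fold (14.0 to 3202).

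Of 867 sites with at least 20 reads in the N2 and fumarate libraries together, 203 were higher in N2 and 267 were lower. No fumarate read was found at 84 of the 203 higher sites, and no N2 read at 201 of the 267 lower sites. The leading N2-higher site was plus 75276, with 363 N2 reads, 0 fumarate reads and 3 electrode reads, at least 112-fold higher. It was followed by minus 3105876, at least 91.5-fold, and by plus 1192911 with 200 N2 reads and none elsewhere, at least 61.8-fold. Minus 2002701, plus 925046, minus 1342593, plus 3628295, plus 3813987 and plus 3641416 had 116 to 171 N2 reads and no fumarate read. Minus 2702515 had 999 N2 reads against 16, 57.9-fold (35.5 to 101.7), minus 944217 had 400 against 4, 92.7-fold (35.9 to 341.9), and plus 3614163 had 489 against 7, 64.8-fold (31.2 to 161.9). Within 100 nt, plus 3628295 had 73 fumarate and 91 N2 reads. The surroundings of plus 1192911 ran the other way, with 20 fumarate reads (161.4 RPM) against 10 N2 reads (74.8 RPM), and the other higher sites named had at most 10 fumarate reads. Among the lower sites, plus 3555956, the leading fumarate site, had 11527 fumarate reads against 38 N2 reads, 327-fold (238.2 to 462.6). Plus 2268271 and minus 808609 were at least 307-fold and 294-fold lower in N2. Plus 1610115, minus 2249749, minus 2818104, minus 751, minus 2079142, plus 225181 and plus 1608762 had 350 to 625 fumarate reads and no N2 read. Minus 3059035 had 872 fumarate reads against 2 N2 reads, 470-fold (129.8 to 3889), and plus 1290281 had 505 against 1, 545-fold (97.3 to 21557). Of these 12 lower sites, plus 1610115 (82.3 RPM N2 against 64.6 fumarate) and plus 225181 (2 N2 reads against 0) had surroundings that ran the other way.

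The 163 sites with at least 20 reads in both libraries had a median ratio 1.56-fold above 1, or 0.64 on the log2 scale. Scaling to it left 135 sites higher and 286 lower, so the higher share of called sites went from 43.2% to 32.1%, and a minimum of 100 reads left 62 higher and 68 lower.

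**Figure D3:**
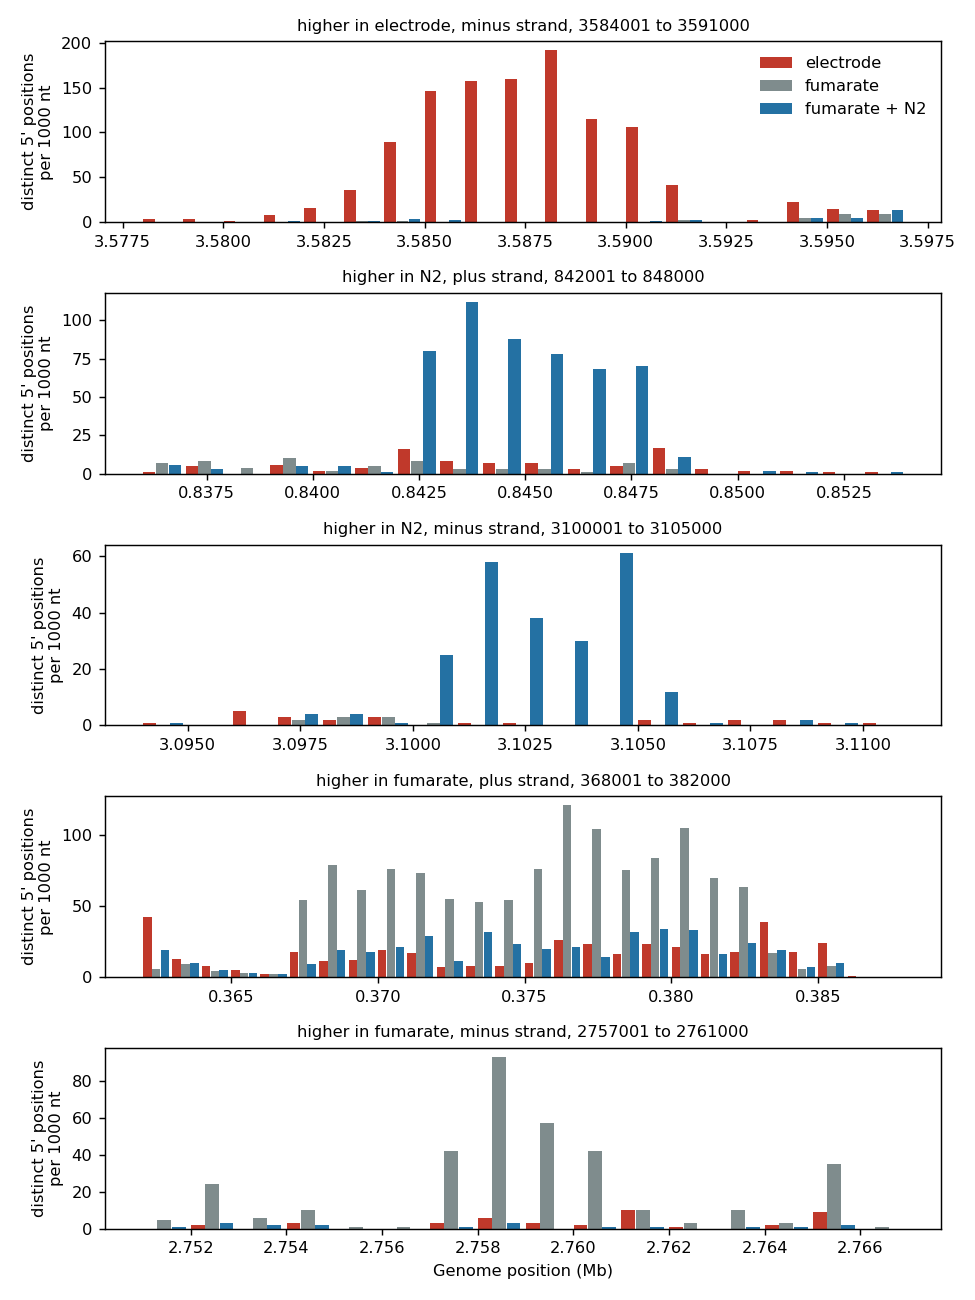
Bars give the number of distinct 5′ positions per 1000 nt on the strand named in each panel, against genome position in Mb, for the electrode, fumarate and N2 libraries. The minus-strand stretch from 3584001 to 3591000 is filled by the electrode library (965 positions), plus 842001 to 848000 and minus 3100001 to 3105000 by the N2 library (496 and 212), and minus 2757001 to 2761000 by the fumarate library (234), while plus 368001 to 382000 holds 1086 fumarate, 323 N2 and 217 electrode positions.

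Both comparisons used the same fumarate library. Among 774 sites with enough reads in both, 245 were lower than fumarate in both and 33 were higher in both. Independent lists of those sizes would share 93.1 and 16.9 sites, and simulated libraries with no difference shared 0 in either direction. The size rule calls nothing on unchanged counts, so that 0 does not measure what a shared library adds. How much of the agreement comes from the single fumarate library was not measured. Its reads can be split into odd and even tiles, but the comparisons were not repeated with these as separate controls. Such a split could address counting error only, since both sets of reads come from the same library.

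Some sites kept similar levels in the 3 libraries. Of 158 sites with at least 20 reads in each, 21 lay within 2-fold from lowest to highest share and 82 spread over more than 4-fold, with a median of 4.14-fold. Minus 1782312 had 673.9, 758.6 and 703.4 RPM in the electrode, fumarate and N2 libraries, a 1.13-fold range. Plus 1263447 had 2711, 2332 and 3090 RPM, a 1.32-fold range, and plus 1196240 had 1209, 1719 and 1489, a 1.42-fold range. These examples were chosen after their values were seen.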

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

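Alternatives for the regional bins, for electrode against N2 and for the shift of minus-strand ends were chosen after seeing the data, the others before. Other scalings shift every site alike, so they could not take the named sites, chosen for large bounds, across 4-fold. Of the other values, 54 stayed within their limits and 54 moved. Causes were not tested unless the setting itself explains them. Site counts at 5 reads were 1424 (fumarate) and 1290 (N2), at 50 reads 762 (electrode), 185 and 224, and after thinning 702.5 (electrode). Sharing of fumarate sites in the electrode library was 29.85% at 5 reads, 43.6% at 50 reads, 43.0% at deposited depth, 30.4% at the same nt and 39.05% within 20 nt. Sharing of fumarate sites in N2 was 28.3% at 5 reads, 28.8% at the same nt and 37.8% within 20 nt. Sharing of electrode sites in N2 was 62.1% at 5 reads, 43.7% at 50 reads, 38.9% at deposited depth and 53.1% at the same nt, and in the fumarate library 30.7% at 50 reads, 21.5% at deposited depth, 33.9% at the same nt and 42.5% within 20 nt. A 2-fold bound gave 453 electrode-higher beside 308 lower sites, and 336 N2-higher beside 304 lower sites. Higher sites then outnumbered lower ones in both comparisons with fumarate. A minimum of 100 reads gave 67 electrode-lower sites beside 220 higher, 62 N2-higher and 68 N2-lower sites, and no minimum gave 473 electrode-lower sites. Median-ratio scaling gave 135 N2-higher sites. For electrode against N2, a 2-fold bound gave 334 higher and 266 lower sites, and a minimum of 100 reads 166 higher and 54 lower. Of the bins, thinning gave 9 electrode-higher and 7 electrode-lower. Reads in place of positions gave 131 and 324 for the electrode and 161 and 137 for N2. A 2-fold bound gave 34 and 63, and 44 and 62. Bins of 5000 nt gave 9 electrode-lower, 13 N2-higher and 8 N2-lower, and bins of 200 nt 12 N2-higher. For electrode against N2, thinning gave 10 higher and 12 lower bins, reads in place of positions 86 and 222, bins of 5000 nt 8 and 12, and a 2-fold bound 39 and 57. Windows of 150 and 500 nt upstream of genes, gene list medians, site classes, leader lengths and base composition were not run, since no site was assigned to a gene. No paired analysis was possible because each condition has 1 library. Depth limits the fumarate and N2 libraries most, where 0 reads allow up to 24.2 and 22.4 RPM.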

Other observations

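The comparison of the electrode and N2 libraries and the sites named in it, the tests of site shape and instrument, the interval on the spacing ratios, and the spacing window of 75 to 150 nt were chosen after the values were seen. So were the use of bootstrap intervals and of subsets of sites for the rank correlations, and the instrument test replaced one on the pooled sites, whose rho of -0.05 depends on how sites were selected. The downstream test, the test of spacing at sites read in 1 library, and the tests of site selection and of amplification for the rank correlations were set out before their results were seen.

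Set directly against each other, 175 sites were higher in the electrode library than in N2 and 154 were lower, of 1349, and with median-ratio scaling the higher share of called sites went from 53.2% to 63.8%. Minus 2031398 was at least 279.5-fold higher in the electrode library, though within 100 nt the N2 library had more (67.3 against 27.6 RPM), and plus 1192911 at least 379.7-fold higher in N2. Minus 1550894 had 581 N2 reads against 16 electrode reads, 207-fold (126.3 to 364.3), and 24 in fumarate. The minus-strand stretch 3234001 to 3238000 held 316 N2 positions against 29 electrode positions, 19.1-fold (13.0 to 28.9), and 51 fumarate positions. The minus-strand stretch 2353001 to 2356000 held 93 electrode, 4 fumarate and 0 N2 positions. After thinning to the same number of reads, 10 of the 16 electrode-higher and 12 of the 35 N2-higher bins of this pair were kept. Called bins lay next to each other more often than chance. The 24 N2-higher bins against fumarate made 15 neighbouring pairs, where 1000 random placements gave at most 5, and the 14 electrode-higher bins made 9 against at most 2.

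Of the 2129 sites, 301 were read in the electrode library alone, 223 in the fumarate library alone and 46 in the N2 library alone, and 71, 19 and 1 of these had at least 100 reads. Depth was not tested, since reads of 1 amplified molecule are not separate draws. Amplification of single molecules may account for many, because private sites of 20 to 1000 reads were sharper than shared ones, with a median difference in reads beside the summit of -7.32 percentage points in the electrode and -8.37 in the fumarate library (one-sided permutation p = 0.0001 each, the smallest that 10000 permutations can give). Part of this difference may come from how sites were defined. The summit was set by reads summed over all libraries, so a shared fumarate site could be centred on the electrode peak. Asking for no reads of the other libraries over the whole site may also favour narrow private sites. Starts used in 1 condition stay open too. The log2 ratio of distinct positions downstream was higher at private sites by 0.84 (one-sided permutation p = 0.0001) in the electrode and 0.62 (permutation p = 0.0004) in the fumarate library. Single molecules drawn from more transcribed regions could give the same result. So could the choice of sites. The ratio divides by positions in a library where private sites were chosen for having no reads and shared sites for having reads. Both tests gave what their explanation predicts, but neither separates the explanations. A site read in 1 library is therefore not by itself a condition-specific start, and N2 had too few such sites to be examined.

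Start sites on opposite strands often faced away from each other at a short distance, with 109 divergent pairs 75 to 150 nt apart and a peak of 49 pairs at 100 to 124 nt, but 77 facing pairs as well, where 1000 rotations of 1 strand, which break up local clusters of sites, gave at most 67 and 50. By library, the electrode sites made 85 divergent pairs (highest rotation 32) and the N2 sites 47 (13). The fumarate sites made 14, within their rotations (highest 18) but 4.65 times the rotated mean, near the 4.80 of all sites. Facing pairs numbered 55 (highest rotation 27) in the electrode, 23 (12) in the N2 and 7 (20) in the fumarate library. Among sites with at least 5 reads in every library there were 13 divergent and 2 facing pairs, 13.7 times (7.30 to 23.45) the rotated mean for divergent pairs, and among sites read in 1 library alone the ratio was 1.89 (0.39 to 5.53) from 3 divergent pairs, beside 8 facing pairs, as many as their highest rotation. Amplified molecules as the source of the spacing stay open, narrowly, because the second ratio was 0.138 times the first with an exact interval of 0.025 to 0.502, which reaches the bound of 0.5 set beforehand and treats pairs as independent; a looser bar considered once the interval was known, an interval below 1, would count against them. A possible explanation for the spacing is divergent promoters between neighbouring transcripts, which was not tested without gene positions.

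Over all sites, with libraries thinned to the same number of reads, read counts of the fumarate library were almost unrelated in rank to those of the others, with Spearman's rho of -0.05 with the electrode and -0.09 with N2, against 0.52 between electrode and N2 (across sites, which are not independent replicates). Selection of sites may account for much of this, because with sites taken from the third library rho rose to 0.75, 0.67 and 0.85, with a gap to the electrode and N2 pair of 0.10 (0.0568 to 0.149) for electrode with fumarate, which leaves that pair open, and 0.18 (0.126 to 0.234) for N2 with fumarate. Of the sites behind 0.85, 40.9% had 0 reads in both libraries, against 9.78% and 14.9% for the other pairs. Such sites raise a rank correlation. Over sites read in both libraries, rho was 0.668, 0.483 and 0.687. The gap was then 0.0195 (-0.0751 to 0.104) for electrode with fumarate and 0.205 (0.101 to 0.300) for N2 with fumarate. Leaving out only sites at 0 in both, it was 0.0847 (0.0255 to 0.144) and 0.266 (0.196 to 0.348). Amplification as a cause stays open. At third-library sites with reads beside the summit, the gap for N2 with fumarate was still 0.20 (0.128 to 0.284), beyond the bound set beforehand. It was 0.23 (0.136 to 0.320) without sites at 0 in both libraries. Over sites read in both it was 0.16 (0.0411 to 0.277), an interval that does not clear the bound. For electrode with fumarate the gap at sites with reads beside the summit was 0.0603 (0.0106 to 0.1145), which decides nothing. Site shape was judged in the third library and not in the libraries compared, so amplified molecules in the compared libraries were not removed. The pairs also rest on different sites. The split by instrument runs the other way, which is the pattern itself and no further test, since electrode sites were found in N2 more often than in the fumarate library of their own instrument by 18.8 percentage points, while a difference of a single lane or preparation, or of biology, cannot be separated with 1 library per condition.

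Reads per 1000 nt and strand were related in rank in all 3 pairs, with rho across bins of 0.65 for electrode with fumarate, 0.60 for N2 with fumarate and 0.67 for electrode with N2. Thinned to the same number of reads, these were 0.58, 0.60 and 0.60. As deposited, bins of 200 nt gave 0.38, 0.29 and 0.29 and bins of 5000 nt 0.775, 0.748 and 0.805.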
